A study of Homo sapiens with 23 samples.

How the data were processed

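RNA was sequenced from 23 cultures of MIA PaCa-2 cells in 8 groups, each of 4 lines being treated with DMSO or 500 nM napabucasin for 2 h. Per the labels, RNA was extracted with TRIzol and columns, and libraries were made with a kit that selects polyadenylated RNA. The submitters' processing notes list FastQC 0.11.5, STAR 2.6.0c, RSEM 1.3.1 and the genome build GRCh38.p12. The annotation release, the strand setting and any filters were not stated. The deposited values are, per the file headers, RSEM expected counts per gene and per transcript, which are estimated reads and not normalized. The deposited transcript tables also give, per the file headers, each transcript's percent of the abundance of its gene, which was used only as an alternative for the exon 5 share. Of all deposited expected counts, 13.29% were not whole numbers (tolerance 0, as deposited with decimals), and they were rounded for the gene tests. Of 58870 genes, 58597 matched GENCODE 29 by identifier and held 99.975% of the counts, and positions, exons and transcripts were taken from that release. Where genes overlap or belong to families of like sequence, their counts depend on a strand setting and on shares of reads that could not be checked. Totals ran from 12499123 to 17185733 counts per library. No intervals were computed for single counts, and the errors given come from replicates or from the model.

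Every sample's group was taken from its label, and the 8 groups formed 1 factor in a model without intercept, so that all libraries shared 1 estimate of spread (common biological coefficient of variation 0.047). Genes were kept by edgeR's filterByExpr with the 8 groups, leaving 15691. Counts were scaled by TMM (factors 0.948 to 1.043), and edgeR 4.0.16 in R 4.3.3 was used for quasi-likelihood tests with robust spread. Values of p were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Log2 fold changes are given with their standard error. These errors, like the p values, reflect the spread of libraries within groups and not the spread between lines. CPM values (counts scaled to the library total) were computed from the deposited expected counts with TMM-scaled totals, and log2 CPM for the principal components used a prior count of 2. The contrasts were the napabucasin response in each line, its differences between guide lines and controls, between Rosa26 and parental cells and between the guide lines, and the baseline differences under DMSO. A difference between responses was always tested as such. Gene lists, 32 in number with 733 genes, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with a correlation estimated per list. Overlaps of genes between lines were tested with Fisher's exact test. Guide sequences were those of the labels, and each was searched with its adjacent NGG motif on both strands of the annotated NQO1 transcripts. The share of NQO1 counts on transcripts without exon 5 came from the deposited expected counts per transcript and was compared by exact permutation of the libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

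The contrasts, tests, gene lists and alternatives were chosen before the data were examined, as was the rule for which genes are named. It took NQO1, then for each contrast up to 8 genes per direction with the largest change among protein-coding genes past the threshold. These also needed a mean of at least 1 CPM. For responses and baselines there had to be no overlap between the libraries compared. For the difference between guide lines and controls, the sign had to be the same in both guides against both controls. As applied, neither condition was set for the differences between Rosa26 and parental cells and between the guide lines. The rule added up to 4 members of each list with the smallest p, and a short set of candidate genes of NRF2 and STAT3 signalling and quinone reduction. Fewer genes than the rule allows are printed, and they are not always those with the largest change, since some of higher rank were passed over. The alternatives were DESeq2's size factors in edgeR, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (at least 5 CPM in at least 2 libraries), a fit to the groups of the contrast alone, a replicate block, and leaving out each library in turn. The 18S-locus share as a covariate on the log2 scale, the removal of NQO1-71 DMSO libraries 1 and 2, the removal of both parental libraries 3, and percent of abundance for the exon 5 share were added after the data had been seen. No library was left out of the reported values.

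The workflow was tested on simulated data with known changes. In a simulated contrast laid out like the parental response, over 15495 genes, it called 50.7% of 67 genes changed 1.25-fold. It called 64.2% of 67 changed 1.5-fold and 90.9% of 66 changed 2-fold, and 7.3% of its calls were unchanged genes. The real parental response had 2971 calls, far more than the simulation changed, and the simulation held no batch differences between libraries. Recovery in the real data may therefore differ. For a simulated difference between responses, over 15497 genes, these shares were 40.3%, 64.2%, 86.4% and 4.8%. Whether replicate numbers pair the samples was checked by correlating replicates across treatments within each line.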

Results

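The series holds messenger RNA sequencing of MIA PaCa-2 (MiaPaCa2), a human pancreatic cancer cell line, after 2 h with 500 nM napabucasin or with the solvent DMSO. Napabucasin is a naphthoquinone described as an inhibitor of STAT3 signalling, and NQO1 encodes a cytosolic quinone reductase. The 4 lines were parental cells, cells with a Rosa26 control vector, and lines with CRISPR guides against NQO1, named NQO1-71 and NQO1-163. Each of the 8 groups had 3 biological replicates except Rosa26 DMSO, which had 2, so that there were 23 libraries. The comparisons ask how each line responded to napabucasin, whether the response differed where NQO1 was targeted, and how the vehicle-treated lines differed. In libraries 1, 2 and 3, parental cells gave totals of 16257383, 14024329 and 15276761 counts with DMSO and 13191189, 14929181 and 12963098 with napabucasin. Rosa26 cells gave 15779307 and 15183253 with DMSO and 14566458, 14232442 and 12499123 with napabucasin. NQO1-71 cells gave 15086291, 12805518 and 16312114 with DMSO and 15570041, 15728090 and 13769741 with napabucasin. NQO1-163 cells gave 17185733, 17128404 and 15686222 with DMSO and 15587645, 14504138 and 14952809 with napabucasin. The first principal component carried 43.7% of the variance and set NQO1-163 (63.84 to 65.77) apart from parental cells (-60.17 to -56.68). The second carried 16.2% and set NQO1-71 apart (38.47 to 41.47).

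Counts on 3 genes beside the ribosomal RNA repeats of chromosome 21 (FP671120.3, FP236383.2 and FP236383.3, here called the 18S-locus genes) differed between libraries. In NQO1-163 cells they took 0.501% ± 0.183 of counts with DMSO and 3.00% ± 0.49 with napabucasin (SD, n = 3 each). In NQO1-71 cells the 3 DMSO libraries had 4.64%, 3.47% and 0.320%, and the napabucasin libraries 0.480% ± 0.103 (SD, n = 3). Other RNAs moved in the same DMSO libraries, with MT-RNR2 at 1.07%, 0.795% and 0.341% and MALAT1 at 0.300%, 0.286% and 0.158%. Parental cells had 2.38% ± 1.74 with DMSO and 2.70% ± 1.58 with napabucasin (SD, n = 3 each). Rosa26 cells had 4.004% ± 0.107 (SD, n = 2) and 3.65% ± 0.23 (SD, n = 3).

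**Figure D1:**
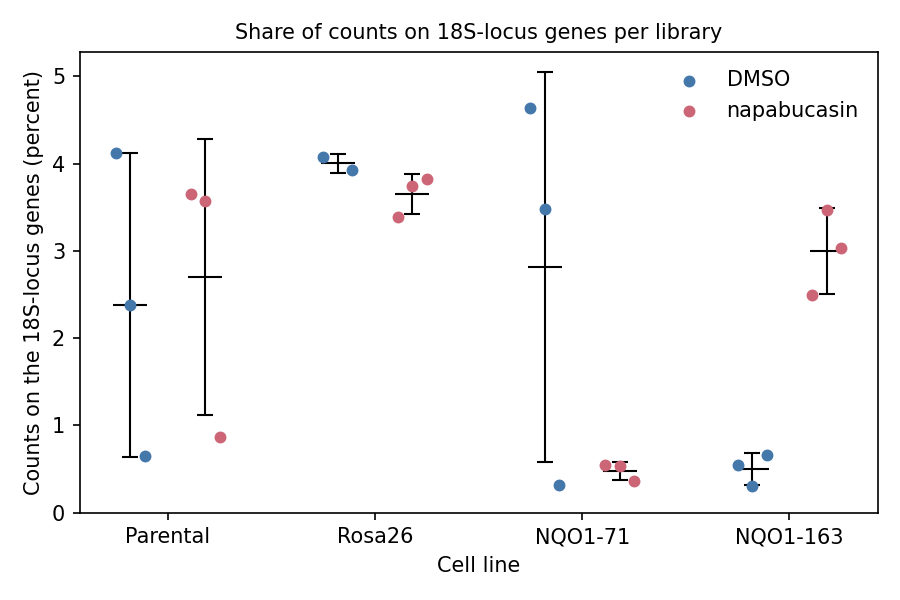
Percent of counts on the 18S-locus genes in each library (points), by group, with the group mean and SD (bars; n = 3 per group, 2 for Rosa26 DMSO). NQO1-163 moved from a mean of 0.501% with DMSO to 3.00% with napabucasin, while 2 of the 3 NQO1-71 DMSO libraries lay far above the napabucasin libraries.

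NQO1 (ENSG00000181019.13, GRCh38 chromosome 16, 69706996 to 69726951) was lower in both guide lines than in both control lines in every library. Parental DMSO libraries had 562, 559 and 597 CPM (counts scaled to the library total) and napabucasin libraries 683, 644 and 701. Rosa26 cells had 419 and 422 CPM with DMSO and 513, 481 and 478 with napabucasin. NQO1-71 cells had 163, 170 and 184 CPM with DMSO and 190.2, 181 and 182 with napabucasin. NQO1-163 cells had 244, 246 and 256 CPM with DMSO and 242, 236 and 235 with napabucasin. Under DMSO, NQO1 was lower in NQO1-71 than in Rosa26 cells (log2 fold change -1.28 ± 0.05, SE, adjusted p = 4.33e-20, edgeR quasi-likelihood test). It was also lower in NQO1-163 than in Rosa26 cells (-0.76 ± 0.05, SE, adjusted p = 4.75e-15). Rosa26 cells themselves had less NQO1 RNA than parental cells (-0.45 ± 0.05, SE, adjusted p = 1.26e-09). NQO1 rose with napabucasin in parental cells (0.24 ± 0.04, SE, adjusted p = 2.97e-05) and in Rosa26 cells (0.22 ± 0.05, SE, adjusted p = 0.00188). Its change did not pass the test in NQO1-71 (0.09 ± 0.04, SE, adjusted p = 0.490) or NQO1-163 cells (-0.07 ± 0.04, SE, adjusted p = 0.390). The response of NQO1 was lower in the guide lines than in the controls by the test of the difference (-0.22 ± 0.04, SE, adjusted p = 0.000616).

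**Figure D2:**
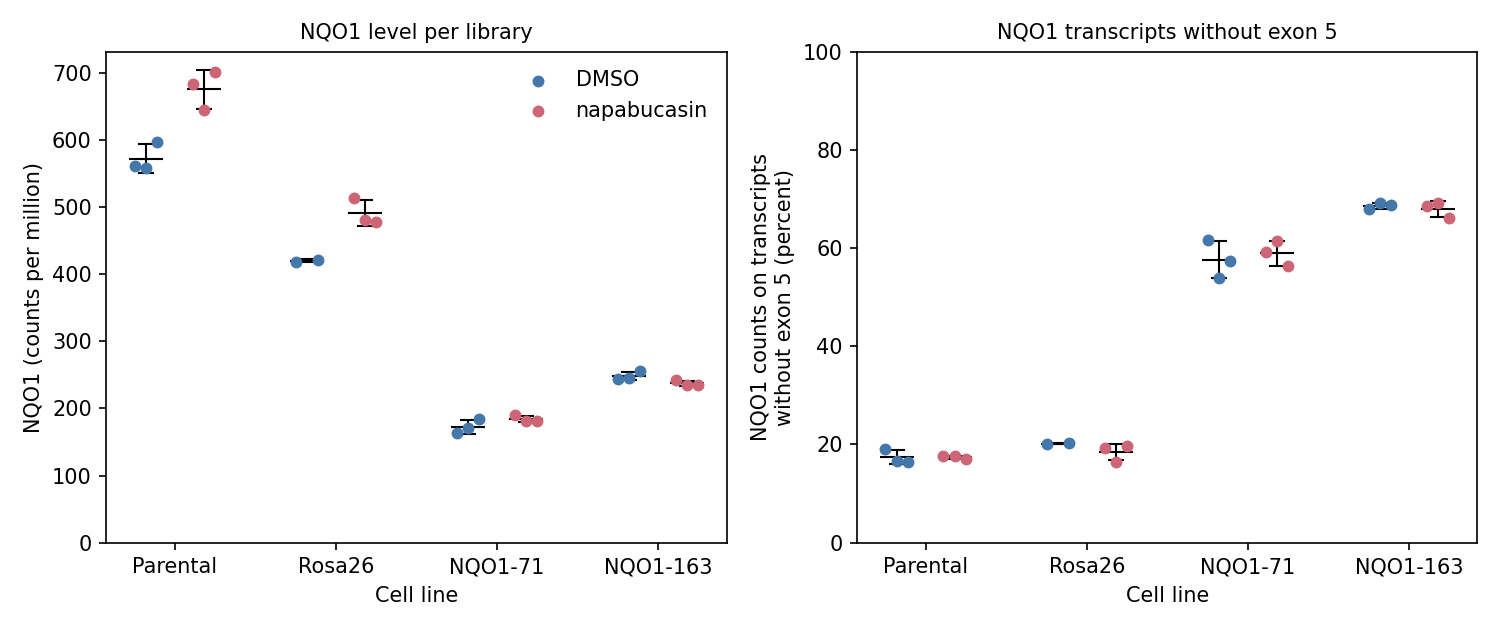
Left, NQO1 level in CPM in each library (points) by group. Right, percent of NQO1 counts on transcripts without exon 5, with group means and SD (bars) in both panels; the guide lines lie below the controls on the left (163 to 256 against 419 to 701) and above them on the right.

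The guides lie in different exons of NQO1, numbered as in transcript NQO1-201. The NQO1-71 guide (TAAGCCAGAACAGACTCGGC, followed by AGG) matches chromosome 16 from 69718199 to 69718218 in exon 3, which all 7 annotated transcripts share. The NQO1-163 guide (GAATGACATTCATGTCCCCG, followed by TGG) matches 69713042 to 69713061 in exon 5, which NQO1-203 lacks. Estimated transcript counts, looked at only after the data had been seen, put more of the NQO1 signal of the guide lines than of Rosa26 cells on transcripts without exon 5. As a percent of counts, that share was 58.3% ± 3.0 in the 6 NQO1-71 libraries and 68.2% ± 1.2 in the 6 NQO1-163 libraries, against 19.1% ± 1.5 in the 5 Rosa26 libraries (SD). Each guide line lay above Rosa26 in every library (exact two-sided permutation p = 0.00216 each, adjusted p = 0.00216 over both tests, 462 arrangements). That p is the smallest these arrangements allow. It compares cell populations, with both treatments pooled, and does not separate the guide from other differences between the lines. By the deposited percent of abundance, also chosen after the data had been seen, the means were 50.5% in NQO1-71, 56.5% in NQO1-163 and 24.4% in Rosa26 libraries. By counts, parental DMSO libraries had 17.3% ± 1.4 (SD, n = 3). Under DMSO, NQO1-201 had 2327 ± 47 counts in Rosa26 (SD, n = 2), 156 ± 74 in NQO1-71 and 41.0 ± 71.0 in NQO1-163 cells (SD, n = 3 each). NQO1-203 had 144 ± 11, 744 ± 131 and 1807 ± 29 counts in the same groups. All transcripts with exon 5 had 5079 ± 59, 1069 ± 192 and 1342 ± 56 counts there, and all without it 1283 ± 4, 1460 ± 286 and 2929 ± 104 (SD). The higher share in NQO1-71 cells thus came mostly from fewer counts with exon 5. NQO1-204 had 1131 and 1136 counts in the Rosa26 DMSO libraries and 669, 559 and 891 in those of NQO1-71. These are values apportioned among transcripts by the model of RSEM and not reads over single exons.

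**Figure D3:**
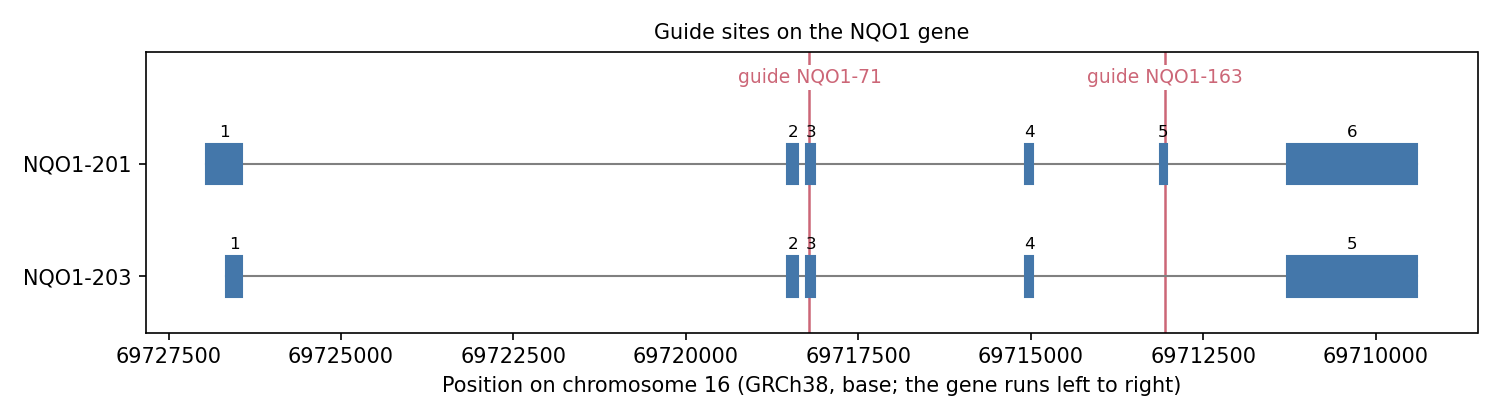
Position of both guides (red lines) on the exons (boxes, numbered) of transcripts NQO1-201 and NQO1-203, along GRCh38 chromosome 16 in bases, with the gene running left to right. The NQO1-71 guide lies in exon 3 of both transcripts, and the NQO1-163 guide in exon 5 of NQO1-201, which NQO1-203 lacks.

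In parental cells napabucasin raised genes of the early stress and growth factor response. FOS (ENSG00000170345.10, chromosome 14, 75278774 to 75282230), a subunit of the AP-1 transcription factor, rose by a log2 fold change of 3.73 ± 0.10 (SE, n = 3 per group, adjusted p = 3.35e-23). ARC, a synaptic immediate early gene, rose by 5.11 ± 0.32, and RGS2 and RGS16, regulators of G-protein signalling, rose by 4.01 ± 0.26 and 3.81 ± 0.19 (SE). ATF3, a stress-induced transcription factor, rose by 3.36 ± 0.10 (SE, adjusted p = 4.79e-22). Among the immediate early genes fixed in advance, 32 of 40 rose and 0 fell (34 and 0 adjusted over the list alone), with a median of 1.40 (camera adjusted p = 1.3e-46), DUSP1 and BTG2 rising by 2.17 ± 0.07 and 2.46 ± 0.08 (SE). Genes that fell included the repressor of receptor tyrosine kinase signalling SPRY1 (-1.11 ± 0.05, SE, adjusted p = 5.86e-18) and the BMP antagonist NOG (-1.16 ± 0.09, SE, adjusted p = 3.86e-11). The largest fall by the naming rule was PALM2-AKAP2 (-2.05 ± 0.47, SE, adjusted p = 0.00347), a readthrough gene whose counts are uncertain.

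Stress programmes moved with these genes in parental cells. Of 34 NRF2 targets, which answer oxidative and electrophilic stress, 16 rose and 3 fell (19 and 4 adjusted over the list alone, camera adjusted p = 1.4e-07). HMOX1 (ENSG00000100292.17), which degrades heme, rose by 1.94 ± 0.10 and OSGIN1 by 2.42 ± 0.11, whereas the redox enzymes SRXN1 and TXNRD1 rose less, SRXN1 by 0.75 ± 0.04 (SE) and TXNRD1 by 0.33 (adjusted p = 5.83e-08). Of 31 targets of ATF4, the transcription factor of the integrated stress response, 18 rose and 0 fell (20 and 0 adjusted over the list alone, camera adjusted p = 1.27e-18). These included ATF4 itself (1.47 ± 0.04), PPP1R15A (1.89 ± 0.07) and DDIT3 (1.58 ± 0.09, SE). Of 30 heat shock targets, 19 rose and 1 fell (21 and 1 adjusted over the list alone, camera adjusted p = 3.93e-16), with the co-chaperones DNAJB1 at 0.72 ± 0.04 and DNAJB4 at 1.81 ± 0.08 (SE). Endoplasmic reticulum chaperones had 8 of 19 up and 2 down (10 and 2 adjusted over the list alone, camera adjusted p = 3.51e-06), and HERPUD1 rose by 1.51 ± 0.05 (SE). Of 27 p53 targets 11 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 4.7e-09), among them the cell cycle inhibitor CDKN1A (2.58 ± 0.15) and the pro-apoptotic PMAIP1 (2.20 ± 0.13, SE). Of 26 hypoxia targets 12 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 6.5e-07), VEGFA by 0.89 ± 0.08 (SE). Ribosomal protein genes, fixed as a sign of RNA quality, moved as well (29 of 35 up and 0 down, 35 and 0 adjusted over the list alone, camera adjusted p = 2.65e-12, adjusted p = 0.231 with an estimated correlation).

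STAT3 targets in parental cells went both ways, with 13 of 25 up and 5 down (13 and 7 adjusted over the list alone, camera adjusted p = 2.19e-05). The feedback inhibitor SOCS3 rose (adjusted p = 2.65e-09), as did MCL1 (0.82 ± 0.03, SE), a survival protein that also stands in the immediate early list. STAT3 RNA itself had a log2 fold change of -0.12 (adjusted p = 0.0142), a call that was lost with no low-count filter (-0.125) and in a fit to the groups of the contrast alone (-0.112). Of 19 NF-kB targets 9 rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0155), NFKBIZ rising by 2.61 ± 0.13 while the chemokine CXCL1 (-0.81 ± 0.09) and the apoptosis inhibitor BIRC3 (-0.70 ± 0.07, SE) fell. Mitotic genes had 3 of 30 up and 10 down (3 and 12 adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.304 with an estimated correlation), with CENPF at -0.52 ± 0.04 (SE). DNA repair genes had 1 of 28 up and 10 down (3 and 10 adjusted over the list alone, camera adjusted p = 0.0221, adjusted p = 0.0781 with an estimated correlation), with the damage kinase ATM at -0.56 ± 0.06 (SE). NFE2L2, which encodes NRF2, rose slightly (0.22, adjusted p = 0.000199), KEAP1, its repressor, had a change of -0.04 (adjusted p = 0.681), and the flavoprotein reductase POR rose by 0.26 ± 0.05 (SE, adjusted p = 0.00031). In all, 1231 genes rose and 1740 fell of 15691 tested, 267 of them over 2-fold. Without both parental libraries 3, an alternative chosen after the data had been seen, 746 rose and 1139 fell.

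In Rosa26 cells immediate early and stress genes rose as well. FOSB, another AP-1 subunit, rose by 2.62 ± 0.14 (SE, n = 2 and 3, adjusted p = 8.57e-12), FOS by 2.32 ± 0.10 (SE, adjusted p = 2.59e-16) and the nuclear receptor NR4A1 by 1.85 ± 0.25 (SE, adjusted p = 6.92e-06). Of the 40 immediate early genes 33 rose and 0 fell (35 and 0 adjusted over the list alone, camera adjusted p = 8.51e-69), with a median of 0.84. Of the 34 NRF2 targets 8 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.9e-10). OSGIN1 rose by 1.80 ± 0.12, HMOX1 by 1.68 ± 0.12, SRXN1 by 0.88 ± 0.04 and TXNRD1 by 0.63 ± 0.04 (SE). ATF4 targets had 12 of 31 up and 0 down (16 and 0 adjusted over the list alone, camera adjusted p = 3.51e-19), with ATF3 at 1.63 ± 0.10 and ATF4 at 0.75 ± 0.04 (SE). Heat shock targets had 9 of 30 up and 0 down (14 and 0 adjusted over the list alone, camera adjusted p = 3.54e-16), with DNAJB4 at 1.13 ± 0.10 and DNAJB1 at 0.62 ± 0.04 (SE). Of 27 p53 targets 9 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 9.47e-09), PMAIP1 by 1.16 ± 0.10 (SE). Of 25 STAT3 targets 10 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 1.27e-07), and STAT3 had a change of 0.00 (adjusted p = 0.988). SPRY1 fell (-0.59 ± 0.05, SE, adjusted p = 2.6e-10), as did TENT5A, a poly(A) polymerase (-0.95 ± 0.08, SE, adjusted p = 1.42e-10). Together 339 genes rose and 201 fell, 47 of them over 2-fold. Leaving out Rosa26 DMSO library 1 or 2 lowered the count of 540 to 296 or 276, with the lone vehicle sample then assumed to vary like the other groups.

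The control lines shared many of the genes past the threshold. Of the genes that rose in parental cells, 294 also rose in Rosa26 cells, where 26.6 were expected (Fisher's exact test, adjusted p = 8.93e-285), and 157 fell in both, where 22.3 were expected (adjusted p = 4.76e-110). The genes up in parental cells had a median log2 fold change of 0.30 there, 0.14 in Rosa26, 0.05 in NQO1-71 and -0.01 in NQO1-163 cells. The genes up in Rosa26 cells had medians of 0.36 there, 0.43 in parental, 0.11 in NQO1-71 and 0.06 in NQO1-163 cells, and each choice of genes favours the line it was made in. Across all 15691 genes, which are not independent replicates, the parental and Rosa26 responses correlated weakly (Pearson r = 0.165).

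In NQO1-71 cells the response was small and included immediate early genes. FOSB rose by 1.28 ± 0.15 (SE, n = 3 per group, adjusted p = 6.88e-05), FOS by 0.81 ± 0.12 (SE, adjusted p = 0.000315) and TRIB1, a pseudokinase, by 0.70 ± 0.09 (SE, adjusted p = 6.49e-05). Of the 40 immediate early genes 18 rose and 0 fell (29 and 0 adjusted over the list alone, camera adjusted p = 4.51e-42), with a median of 0.31. ATF4 targets had 4 of 31 up and 0 down (12 and 0 adjusted over the list alone, camera adjusted p = 3.83e-09), including PPP1R15A at 0.42 ± 0.07 and CEBPB at 0.44 ± 0.08 (SE). Of 34 NRF2 targets 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.0378, adjusted p = 0.0967 with an estimated correlation). SRXN1 (0.21 ± 0.04) and MAFG (0.28 ± 0.05) rose, and TXNIP, an inhibitor of thioredoxin, fell (-0.21 ± 0.04, SE). The SRXN1 call was lost in a fit to the groups of the contrast alone (0.196). HMOX1 had a change of 0.19 (adjusted p = 0.658) and TXNRD1 of 0.08 (adjusted p = 0.475). None of the 30 heat shock targets passed over all genes (2 up and 0 down adjusted over the list alone), although the list as a whole lay higher (camera adjusted p = 0.000822, adjusted p = 0.401 with an estimated correlation). The histone gene HIST1H4E fell (-2.11 ± 0.46, SE, adjusted p = 0.0306), but it belongs to a multigene family, its call was lost with the 18S-locus share as a covariate, and that share was higher in 2 of the 3 DMSO libraries. In total 55 genes rose and 18 fell, 10 over 2-fold, but with no low-count filter 72 rose and 78 fell. The count of 73 was 39 without NQO1-71 DMSO library 2, 125 without DMSO library 3 (52 up and 73 down), and 45 or 37 without napabucasin library 1 or 2. With only DMSO library 3, an alternative chosen after the data had been seen, it was 22.

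In NQO1-163 cells immediate early genes also rose. FOSB rose by 1.25 ± 0.14 (SE, n = 3 per group, adjusted p = 4.5e-05), FOS by 0.80 ± 0.09 (SE, adjusted p = 2.5e-06), NR4A1 by 1.40 ± 0.23 (SE, adjusted p = 0.000662) and TRIB1 by 0.73 ± 0.09 (SE, adjusted p = 4.5e-05). Of the 40 immediate early genes 19 rose and 0 fell (24 and 0 adjusted over the list alone, camera adjusted p = 4.58e-18), with a median of 0.21. The share of counts on the 18S-locus genes was 3.00% with napabucasin against 0.501% with DMSO in the same libraries, and with it as a covariate, chosen after the data had been seen, 9 of these 19 genes stayed past the threshold, while their median went from 0.45 to 0.44. Of 34 NRF2 targets 2 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.839), MAFG by 0.21 ± 0.05 and TXNIP by -0.24 ± 0.03 (SE), MAFG losing its call with the covariate (0.145). HMOX1 had a change of 0.14 (adjusted p = 0.479) and TXNRD1 of 0.02 (adjusted p = 0.773). ATF4 targets had 1 of 31 up and 0 down (1 and 0 adjusted over the list alone, camera adjusted p = 0.342). None of 35 ribosomal protein genes passed over all genes (0 up and 27 down adjusted over the list alone, median -0.12, camera adjusted p = 1.8e-12, adjusted p = 0.354 with an estimated correlation). ERK pathway output had 5 of 21 up and 0 down (7 and 0 adjusted over the list alone, camera adjusted p = 0.00385, adjusted p = 0.0821 with an estimated correlation), SPRY4 by 0.35 ± 0.05 (SE), a call lost with the covariate (0.223). The largest rises by the naming rule were the histone genes HIST1H2AM (2.02 ± 0.56, SE, adjusted p = 0.0484) and HIST1H1E (1.70 ± 0.43, SE, adjusted p = 0.0364), members of a multigene family that moved with the 18S-locus share. In total 430 genes rose and 126 fell (23 over 2-fold), but with size factors of DESeq2 in edgeR 354 rose and 324 fell, with DESeq2 351 and 635, and with the covariate 14 and 1. The count was 160, 254 or 208 without DMSO library 1, 2 or 3, and 348, 72 or 115 without napabucasin library 1, 2 or 3.

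Some rising genes were shared between the guide lines and with the controls. Of the rising genes, 26 rose in both guide lines, where 1.5 were expected (Fisher's exact test, adjusted p = 4.7e-26). FOSB rose by 1.28 in NQO1-71 and 1.25 in NQO1-163 cells, FOS by 0.81 and 0.80, and JUNB by 0.48 and 0.46. Of the genes that rose in Rosa26 cells, 47 rose in NQO1-71 cells (1.2 expected, adjusted p = 8.4e-71) and 52 in NQO1-163 cells (9.3 expected, adjusted p = 3.68e-24). ZNF483 went opposite ways, named here after its values were seen, at -1.16 ± 0.23 in NQO1-71 and 0.75 ± 0.22 in NQO1-163 cells (SE). Its call in NQO1-71 cells was lost with limma-voom (-1.04) and with the groups of the contrast alone (-1.17), where its size changed little. With the covariate the call was lost at a smaller size (-0.63), and ZNF483 was not among the 15 genes of NQO1-163 cells with the covariate. Across all 15691 genes, which are not independent replicates, the responses of the guide lines had a Pearson r of -0.096 with each other, and Rosa26 cells one of -0.007 with NQO1-71 and 0.036 with NQO1-163 cells.

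**Figure D4:**
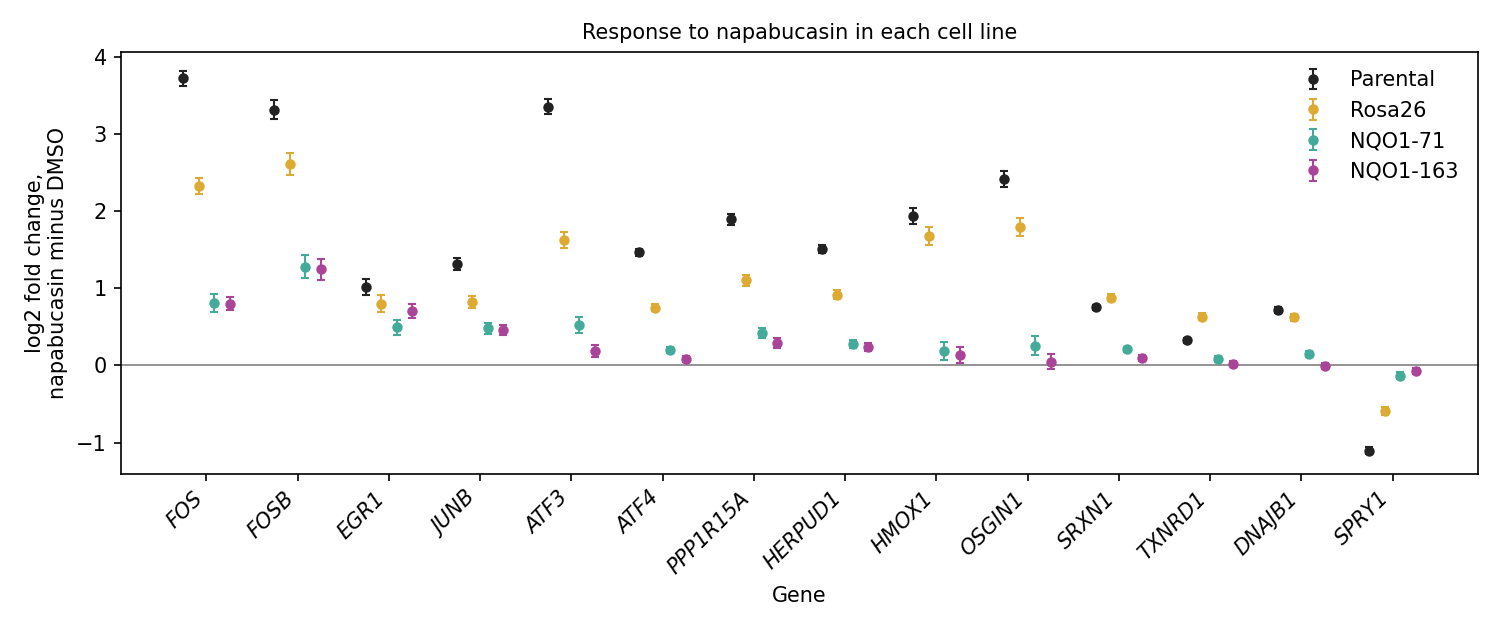
Log2 fold change with napabucasin (points, with SE as bars) of 14 genes in the 4 lines. FOS moved by 3.73 in parental, 2.32 in Rosa26, 0.81 in NQO1-71 and 0.80 in NQO1-163 cells, and HMOX1 by 1.94, 1.68, 0.19 and 0.14.

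The test of whether the response differed between guide lines and controls gave lower responses of stress genes in the guide lines. Among all lower responses, the naming rule ranked TENT5C first (-2.90 ± 0.33, SE, adjusted p = 1.46e-07). The difference for FOS was -2.22 ± 0.11 (SE, 6 guide and 5 or 6 control libraries per treatment, adjusted p = 1.06e-15), for ATF3 -2.14 ± 0.10 (SE, adjusted p = 6.87e-16) and for RGS16 -2.79 ± 0.21 (SE, adjusted p = 3e-11). These errors and p values come from the spread of replicate libraries within each line and do not measure the spread between lines. HMOX1 differed by -1.64 ± 0.11 (SE, adjusted p = 1.11e-12), OSGIN1 by -1.96 ± 0.11 (SE, adjusted p = 5.05e-14), SRXN1 by -0.67 ± 0.04 and TXNRD1 by -0.43 ± 0.04 (SE, adjusted p = 1.05e-09). Of 34 NRF2 targets 12 responded less and 1 more (15 and 2 adjusted over the list alone, camera adjusted p = 1.63e-08). Of 40 immediate early genes 31 responded less and 3 more (32 and 3 adjusted over the list alone, camera adjusted p = 3.44e-35), with a median of -0.72. Most of these 40 genes were already higher under DMSO in the average of the guide lines against the controls, as given below. A smaller fold change therefore need not mean a lower level with napabucasin. Of 30 heat shock targets 17 responded less and 0 more (21 and 0 adjusted over the list alone, camera adjusted p = 3.16e-19), DNAJB1 by -0.60 ± 0.04 (SE). Of 31 ATF4 targets 15 responded less and 0 more (16 and 0 adjusted over the list alone, camera adjusted p = 5.21e-16), ATF4 by -0.96 ± 0.04 (SE). Of 27 p53 targets 8 responded less and 0 more (9 and 0 adjusted over the list alone, camera adjusted p = 6.03e-08), PMAIP1 by -1.51 ± 0.10 (SE). STAT3 targets had 11 of 25 lower and 5 higher (12 and 5 adjusted over the list alone, camera adjusted p = 7.71e-05), with SOCS3 at -0.49 (adjusted p = 0.0109), and STAT3 itself differed by 0.19 (adjusted p = 0.0025). Responses that were higher in the guide lines included SPRY1 (0.75 ± 0.05, SE, adjusted p = 1.13e-13), which had fallen in both control lines, and SPRY4 (0.33 ± 0.05, SE, adjusted p = 1.69e-05). ERK pathway output had 8 of 21 higher and 1 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.00217), and YAP targets 8 of 19 higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.000586). None of the 17 other quinone and flavin reductases differed (0 adjusted over the list alone, camera adjusted p = 0.122). In all 1091 genes responded higher and 849 lower in the guide lines, 93 of them by over 2-fold, whereas size factors of DESeq2 in edgeR gave 959 and 983, and DESeq2 843 and 907. Ribosomal protein genes, fixed as a sign of RNA quality, also responded less (27 of 35 lower and 0 higher, 35 and 0 adjusted over the list alone, camera adjusted p = 1.89e-17, adjusted p = 0.143 with an estimated correlation). Without Rosa26 DMSO library 2, with the lone vehicle sample assumed to vary like the other groups, the count of 1940 became 1264.

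The control lines also differed from each other. The responses of RGS2 (-3.61 ± 0.54, SE, adjusted p = 9.42e-05), ATF3 (-1.73 ± 0.16, SE, adjusted p = 9.65e-09), FOS (-1.40 ± 0.16, SE, adjusted p = 1.38e-06) and ATF4 (-0.72 ± 0.06, SE, adjusted p = 4.28e-09) were lower in Rosa26 than in parental cells. Of 40 immediate early genes 16 responded less and 1 more (20 and 4 adjusted over the list alone, camera adjusted p = 7.61e-16), and of 31 ATF4 targets 6 less and 0 more (8 and 0 adjusted over the list alone, camera adjusted p = 7.06e-09). NRF2 targets had 2 of 34 lower and 1 higher (2 and 2 adjusted over the list alone, camera adjusted p = 0.356). HMOX1 differed by -0.26 (adjusted p = 0.578), and TXNRD1 responded more in Rosa26 cells (0.31 ± 0.06, SE, adjusted p = 0.00122). Heat shock targets had 6 of 30 lower and 0 higher (7 and 0 adjusted over the list alone, camera adjusted p = 3.12e-06, adjusted p = 0.232 with an estimated correlation). In all 141 genes were higher and 126 lower, 41 by over 2-fold, whereas a fit to the groups of the contrast alone gave 75 and 105. The count of 267 was 116 (40 higher and 76 lower), 133 or 177 without Rosa26 DMSO library 1, DMSO library 2 or napabucasin library 2, the lone vehicle sample being assumed to vary like the other groups, and 163 without both parental libraries 3, an alternative chosen after the data had been seen, while the covariate gave 456.

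Histone genes had the largest differences in response between the guide lines by the naming rule. HIST2H2BF (4.24 ± 0.93, SE, adjusted p = 0.0477), HIST1H1E (3.49 ± 0.61, SE, adjusted p = 0.0161) and HIST1H4E (2.90 ± 0.62, SE, adjusted p = 0.0282) were higher in NQO1-163 than in NQO1-71 cells. These belong to a multigene family, and they moved with the 18S-locus share, which was higher with napabucasin in NQO1-163 cells and lower in NQO1-71 cells. HIST1H4E also fell with napabucasin in Rosa26 cells (-1.49 ± 0.42, SE, adjusted p = 0.0481), where the mean share moved little (4.004% to 3.65%). SERTAD1, a cell cycle regulator, responded less in NQO1-163 cells (-0.39 ± 0.08, SE, adjusted p = 0.0261). None of the 40 immediate early genes differed over all genes or adjusted over the list alone (camera adjusted p = 0.111). In all 112 genes were higher and 6 lower, 33 by over 2-fold, whereas DESeq2 gave 60 and 246, and edgeR with the 18S-locus share as a covariate gave 0 of 15691 (637 at an unadjusted p below 0.05). Without NQO1-71 DMSO library 1, 2 or 3 the count of 118 was 3, 0 or 599 (1879 at an unadjusted p below 0.05 for the 0), without its napabucasin library 1, 2 or 3 it was 20, 47 or 27, without NQO1-163 DMSO library 1, 2 or 3 it was 26, 50 or 17, and without its napabucasin library 1, 2 or 3 it was 77, 3 or 4.

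Under DMSO the lines differed in many genes. Compared with Rosa26, NQO1-71 cells had more of the axon guidance gene SEMA6A (log2 fold change 4.83 ± 0.26, SE, n = 3 and 2, adjusted p = 2.42e-15). They had less SAMSN1 (-6.53 ± 0.44, SE, adjusted p = 5.79e-13), CLEC2B (-6.32 ± 0.39, SE) and the actin-binding MARCKS (-6.00 ± 0.39, SE). NR5A2, a nuclear receptor of the pancreas, had 2.65 ± 0.13 CPM in Rosa26 cells (SD, n = 2) and was listed at 0 in NQO1-71 cells. The epithelial keratin KRT19 was lower (-1.94 ± 0.10, SE, adjusted p = 1.85e-16), and the ERK phosphatase DUSP6 was higher (1.25 ± 0.08, SE, adjusted p = 5.1e-13). ERK pathway output had 9 of 21 up and 1 down (10 and 1 adjusted over the list alone, camera adjusted p = 0.00458, adjusted p = 0.118 with an estimated correlation). In total 1785 genes were higher and 1653 lower. The count of 3438 was 1888 without Rosa26 DMSO library 1, the other then assumed to vary like the other groups, and 2080 with NQO1-71 DMSO library 3 alone, chosen after the data had been seen.

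NQO1-163 cells differed from Rosa26 cells in 6263 genes under DMSO, 2956 higher and 3307 lower. AGR2, a disulfide isomerase of secretory epithelia, had 25.8 ± 0.4 CPM in NQO1-163 cells (SD, n = 3) and was listed at 0 in Rosa26 cells. The transporter ABCA8 went the other way, with 12.9 ± 0.5 CPM in Rosa26 cells (SD, n = 2), and was listed at 0 in NQO1-163 cells. The pentraxin PTX3 had 36.1 ± 0.4 CPM in Rosa26 (SD, n = 2) and 0.0187 ± 0.0323 in NQO1-163 cells (SD, n = 3). Among NRF2 targets, the cystine transporter SLC7A11 was higher (1.87 ± 0.11, SE, adjusted p = 6.81e-14) and GCLM, a subunit of the first enzyme of glutathione synthesis, was lower (-1.67 ± 0.05, SE, adjusted p = 2.32e-22). STAT3 was lower (-0.88 ± 0.05, SE, adjusted p = 1.94e-16). ATF4 targets had 21 of 31 up and 4 down (21 and 5 adjusted over the list alone, camera adjusted p = 0.000275, adjusted p = 0.0777 with an estimated correlation).

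Rosa26 cells differed from parental cells in 6663 genes under DMSO, 3251 higher and 3412 lower. The adhesion molecule VCAM1 was higher (7.87 ± 0.26, SE, adjusted p = 1.19e-21), as was the stress cytokine GDF15 (3.64 ± 0.24, SE, adjusted p = 5.09e-14). The ferritin subunits FTH1 (-1.29 ± 0.04, SE, adjusted p = 6.07e-21) and FTL (-1.21 ± 0.05, SE, adjusted p = 3.42e-18) were lower, as was STAT3 (-1.20 ± 0.04, SE, adjusted p = 1.44e-20). Of 31 ATF4 targets 22 were higher and 1 lower (22 and 1 adjusted over the list alone, camera adjusted p = 5.06e-07), with the amino acid transporter subunit SLC3A2 at 1.01 ± 0.06 (SE). NRF2 targets had 6 of 34 up and 17 down (6 and 17 adjusted over the list alone, camera adjusted p = 0.00625). DNA replication genes had 25 of 35 up and 4 down (25 and 6 adjusted over the list alone, camera adjusted p = 2.83e-05), with the helicase subunit MCM7 at 0.50 ± 0.04 (SE). Mitotic genes had 1 of 30 up and 21 down (1 and 23 adjusted over the list alone, camera adjusted p = 5.06e-07, adjusted p = 0.0613 with an estimated correlation), with the kinase AURKA at -0.56 ± 0.04 (SE).

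Setting both guide lines against both controls under DMSO, 7273 genes differed, 3555 higher and 3718 lower. Of these, 3454 had the same sign in each guide line against each control, while pairing the lines otherwise, NQO1-71 with parental against NQO1-163 with Rosa26, gave 7966. HMGA2, an architectural chromatin protein, had 0.0205 CPM in parental, 2.31 ± 0.25 in Rosa26, 3.84 ± 0.60 in NQO1-71 and 41.7 ± 1.7 CPM in NQO1-163 cells (SD). ABCA6, a lipid transporter, had 12.7 ± 1.2 CPM in parental, 1.52 ± 0.12 in Rosa26 and 0.0225 in NQO1-71 cells and was listed at 0 in NQO1-163 cells (SD). DUSP6 was higher in the guide lines (2.82 ± 0.07, SE, adjusted p = 9.74e-25), with 29.3 ± 2.2 CPM in NQO1-71 and 26.3 ± 1.3 in NQO1-163 against 12.3 ± 1.2 in Rosa26 and 1.24 ± 0.13 in parental cells (SD). STAT3 was lower in the averaged contrast (-1.06 ± 0.03, SE, adjusted p = 6.99e-24), but NQO1-71 cells (94.8 ± 2.0 CPM) lay close to Rosa26 cells (97.2 ± 0.8), between parental (224 ± 8) and NQO1-163 cells (52.9 ± 0.9, SD). The averaged fall of FTH1 (-0.82 ± 0.03, SE, adjusted p = 2.52e-21) likewise rested mostly on parental cells, with 2091 ± 53 CPM there, 855 ± 4 in Rosa26, 762 ± 18 in NQO1-71 and 749 ± 41 in NQO1-163 cells (SD). NQO1 differed by -1.24 ± 0.03 (SE, adjusted p = 1.96e-25). Of 40 immediate early genes 29 were higher and 3 lower (30 and 4 adjusted over the list alone, camera adjusted p = 2.1e-05). ERK pathway output had 14 of 21 higher and 4 lower (15 and 4 adjusted over the list alone, camera adjusted p = 0.00107). NRF2 targets had 11 of 34 up and 14 down (11 and 16 adjusted over the list alone, camera adjusted p = 0.463).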

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

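The tests on exon 5 were chosen only after the transcript counts had been seen, as was the pairing of whole lines for the difference between guide lines and controls, and the covariate for the 18S-locus share was added after that share had been seen.

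The napabucasin response differed between the guide lines and the controls in 1940 genes by the test of the difference. Moving whole lines, the 4 lines can be paired in 3 ways, too few for a share under 0.05, and the highest of the other pairings gave 401 genes (1 of 3 as large). Permuting treatment within each line instead, the highest of the others gave 134 genes (1 of 50 as large), but this takes the response away in every line and so tests for any response to napabucasin and not for a difference between guide lines and controls. The pairing of whole lines therefore replaced it.

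The response also differed between the control lines, in 267 genes, and was larger in parental than in Rosa26 cells. The smaller number of Rosa26 DMSO libraries is argued against as the cause, since with 2 parental DMSO libraries the parental count was still at least 2191, against 540 in Rosa26 cells. With the 18S-locus share as a covariate the genes that differed numbered 456, and all 267 were among them. The mean share moved little with napabucasin in parental (2.38% to 2.70%) and Rosa26 cells (4.004% to 3.65%). The covariate could therefore hardly lower this count, and it decides little about carry-over of ribosomal RNA. The vector, the selection or the passage of the Rosa26 cells may account for the difference, but the labels give nothing to test them with, and they remain untested.

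The responses of the guide lines differed in 118 genes, and this pattern is weighed with the response of NQO1-163 cells, since the 18S-locus share moved with both. With the share as a covariate, the NQO1-163 response went from 556 to 15 genes (14 kept, median size of the 556 from 0.26 to 0.15, SE 0.061 to 0.070) and the difference from 118 to 0 (637 at an unadjusted p below 0.05 in edgeR; median 0.56 to 0.21, SE 0.122 to 0.121). Both are consistent with carry-over of ribosomal RNA, or with whatever RNA preparation moves with it, as a candidate cause of most calls, though the share nearly follows treatment in NQO1-163 cells, so that its slope rests on the other groups. Of the 19 immediate early genes that rose in NQO1-163 cells 9 stayed past the threshold, fewer than the share set beforehand for a kept pattern. The median size of the 19 (0.45 to 0.44, SE 0.07 to 0.09), looked at only afterwards, pointed the other way. Single genes that stayed called moved either way, EGR1 from 0.71 to 0.46 and NR4A3 from 1.22 to 1.55. Why the other calls were lost was not tested. For the difference, 4 of 50 regroupings with treatment permuted within each line, the real one included, gave at least as many genes, the highest other 1091. This permutation takes the response away in both guide lines, so it does not test whether their responses differ. It shows only that regrouped libraries can give as many calls, and chance was not excluded. A regrouping with several times the real count points to a structure of the samples.

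The share of NQO1 counts on transcripts without exon 5 was 58.27% in NQO1-71 and 68.23% in NQO1-163 libraries, above the 19.14% of Rosa26, a signal in transcript tables that the gene comparisons do not use. For NQO1-71 the guide lies in exon 3, which is in every annotated transcript. The lowest library (53.96%) lay above the highest of Rosa26 (20.26%), as it did by percent of abundance (47.17% against 25.74%). That is the pattern itself, however, and lost exon 3 reads could weigh unequally on transcripts of unlike length. Whether reads lost at the guide's site shaped the share in NQO1-71 cells was therefore not decided. For NQO1-163 (lowest library 66.01%) lost reads and exon skipping cannot be told apart, because the guide lies in exon 5 itself. A change in splicing, or a mix of edited alleles with and without the exon, may underlie the shift in either line, which reads over exon junctions would test.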

How the results depend on the processing

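The covariate for the 18S-locus share, the removal of NQO1-71 DMSO libraries 1 and 2, the removal of both parental libraries 3 and the percent of abundance for the exon 5 share were added only after the data had been seen. Under the other scalings, filters, tools and fits, every total count of genes not named here stayed within 1.5 times its reported value, while the division into higher and lower moved further. With no low-count filter the counts were 150 in NQO1-71 cells, 961 in NQO1-163 cells and 334 for the difference between the guide lines. The stricter filter gave 871 in NQO1-163 cells, and fitting the groups of the contrast alone gave 40 in NQO1-71 and 1173 in NQO1-163 cells. A replicate block gave 999 in NQO1-163 cells and 235 for the difference between the guide lines, but the numbers were not taken to pair the samples, since 3 of 11 same-number pairs correlated above 0.1 and 3 of 11 correlated best with their own number, although parental libraries 3 correlated best with each other (0.39) and had a lower 18S-locus share than the other parental libraries. DESeq2 gave 986 in NQO1-163 cells (370 shared) and 306 for that difference (15 shared, with 14602 genes left without an adjusted p by its own filter). The covariate gave 15, 456 for Rosa26 against parental responses and 0 between the guide lines (637 at an unadjusted p below 0.05 in edgeR). Without NQO1-71 DMSO libraries 1 and 2, where the lone vehicle sample is assumed to vary like the other groups, the counts were 22 in NQO1-71 cells (20 shared), 2080 at baseline against Rosa26, and 0 between the guide lines in edgeR (852 at an unadjusted p below 0.05). Without both parental libraries 3 they were 1885 in parental cells (1807 shared) and 163 for Rosa26 against parental responses. Except for the fewer libraries or genes in some of these settings, the cause was not tested. Leaving out 1 library at a time gave 2182 to 2700 genes in parental, 276 to 475 in Rosa26, 37 to 125 in NQO1-71 and 72 to 348 in NQO1-163 cells. It gave 1264 to 2219 for guides against controls, 116 to 231 for Rosa26 against parental responses and 0 to 599 between the guide lines, a lone Rosa26 DMSO library being assumed to vary like the other groups. The baselines ran from 1888 to 3252 for NQO1-71, 4725 to 5860 for NQO1-163 and 5142 to 6199 for Rosa26 against parental cells, and from 6379 to 7098 for guides against controls. Of 330 list tests 137 passed with the preset correlation and 59 with an estimated correlation, and fry called change in either direction in 257. Of 226 calls of named genes, 224 were kept with DESeq2's size factors in edgeR, 215 with limma-voom, 221 with no filter and 205 with the covariate, under which HIST1H2AM turned from 3.65 to -0.026 between the guide lines. By percent of abundance the share of NQO1 without exon 5 was 50.54% in NQO1-71 and 56.49% in NQO1-163 libraries, against 58.27% and 68.23% by counts. The difference of NQO1 under DMSO between guides and controls was -1.30 to -1.19 over all alternatives. At this depth and number of libraries 50.7% of 67 simulated 1.25-fold changes were recovered in a contrast laid out like the parental response. Small changes can thus be missed, though the simulation changed far fewer genes than the real response and held no batch differences. The splits of the libraries were too few for a share under 0.05, for parental (2971 against 0 in the highest other, 1 of 10), NQO1-71 (73 against 0, 1 of 10) and NQO1-163 cells (556 against 0, 1 of 10) and for the baseline of guides against controls (7273 against 7966, 2 of 3).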

Other observations

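The covariate test quoted here was chosen only after the 18S-locus share had been seen.

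As a list, genes of BMP and TGF-beta signalling lay higher with napabucasin in a control line and in a guide line. In Rosa26 cells 7 of 17 rose and 0 fell (10 and 1 adjusted over the list alone, camera adjusted p = 3.72e-05), and in NQO1-71 cells 4 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 1.59e-07). In NQO1-71 cells ID1, an inhibitor of basic helix-loop-helix factors, rose by 0.21 ± 0.04 (SE, n = 3 per group, adjusted p = 0.00163). In NQO1-163 cells 2 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00659, adjusted p = 0.0682 with an estimated correlation). The list was not past the threshold in parental cells (camera adjusted p = 0.0807), and the difference between guide lines and controls was not either (adjusted p = 0.645). As a list, sterol genes under SREBP2 lay higher with napabucasin in parental, NQO1-71 and Rosa26 cells, though most members did not pass. In parental cells 6 of 21 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 7.73e-05). In NQO1-71 cells 1 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.000146). In Rosa26 cells 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00116, adjusted p = 0.0729 with an estimated correlation). In Rosa26 cells INSIG1, which retains the SREBP machinery in the endoplasmic reticulum, rose by 0.49 ± 0.07 (SE). In NQO1-163 cells 1 of the sterol genes rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.839).

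Interferon-stimulated genes were higher in NQO1-163 than in Rosa26 cells under DMSO, with 11 of 20 up and 2 down (13 and 2 adjusted over the list alone, camera adjusted p = 0.00387). IFIH1, a sensor of double-stranded RNA, was higher by 2.70 ± 0.37 (SE, n = 3 and 2, adjusted p = 5.23e-07) and BST2, which tethers virions, by 2.15 ± 0.24 (SE, adjusted p = 8.35e-09). None of the 20 passed in the response of either guide line, over all genes or adjusted over the list alone (camera adjusted p = 0.422 in NQO1-71 and 0.872 in NQO1-163 cells). Ribosomal protein genes, fixed as a sign of RNA quality, rose together in parental cells (29 of 35 up and 0 down, 35 and 0 adjusted over the list alone, camera adjusted p = 2.65e-12, adjusted p = 0.231 with an estimated correlation), as did proteasome subunits (11 of 31 up and 0 down, 15 and 0 adjusted over the list alone, camera adjusted p = 8.55e-06, adjusted p = 0.281 with an estimated correlation). In the guide lines against the controls, 27 of the 35 ribosomal protein genes and 14 of the 31 proteasome genes responded less (camera adjusted p = 1.89e-17 and 5.91e-10, adjusted p = 0.143 for each with an estimated correlation). None of the markers of fibroblasts, leukocytes or endothelium that were measured (2, 3 and 1 genes) passed the test over all genes in any of the 4 responses in edgeR, but the response of 1, the collagen gene COL1A2, differed between guide lines and controls (0.24 ± 0.05, SE, adjusted p = 0.00411), a value singled out after it was seen.

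A hypothesis is that the lower stress response of the guide lines may depend on NQO1. The test of the difference gave 1940 genes, and with the 18S-locus share as a covariate 2152, of which 1923 were the same. With napabucasin the mean share rose in NQO1-163 cells (0.501% to 3.00%) and fell in NQO1-71 cells (2.81% to 0.480%). These moves largely cancel in the averaged contrast, so the covariate could hardly lower its count and decides little about carry-over of ribosomal RNA. Both lines with less NQO1 than Rosa26 cells had responses of HMOX1, OSGIN1, FOS and ATF3 that were lower on average than in the controls. Against a simple reading, the control lines differed in 267 genes without a guide against NQO1, and the guide lines differed from the controls in 7273 genes before treatment, 3454 of them with the same sign for each guide line against each control. The design has 1 population per guide and no line with NQO1 put back, so it does not separate the loss of NQO1 from other differences between the populations.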
